A study of Homo sapiens with 4 samples.

How the data were processed

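Gene expression was measured in MOLM-14 cells on 4 single-channel arrays, 2 from control cultures and 2 from cultures exposed to 10 nM rapamycin for 24 hours. The values deposited by the authors are log2 expression values, 1 per probe set and array. RMA and Partek are named in the submitters' processing notes, without versions and without a statement of which step each carried out. RMA corrects the background of each array, makes the distributions of the arrays alike by quantile normalization and summarises the probes of a probe set as a log2 value. The log2 scale was read from the values themselves, which ran from 1.81 to 13.3 with like medians on all 4 arrays. Per the labels' protocols, total RNA was amplified with a whole-transcript kit and the resulting DNA was fragmented and tagged with biotin. The genome build and the treatment of probes that match several genes are not given in the sources used here, so no coordinates are printed.

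Groups were taken from the agent named in each sample's labels, and replicate numbers from the sample titles. The growth and treatment protocols in the same labels describe MOLM-14 cells carrying inducible short hairpin RNAs, either scrambled or directed at PIM2, and grown with doxycycline. The series design and the agent labels describe rapamycin instead. The comparison follows the design and the agent, and whether the cultures also carried a hairpin is left open. The design calls the arrays biological replicates, and nothing further states that they came from separate cultures. The p-values therefore measure the spread between these arrays, which may be technical in part.

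Each of the 25582 probe sets carries an Entrez gene number. The platform annotation gave 1 gene symbol for 24244 of them, several for 0 and none for 1338. Of the Entrez numbers, 24195 were found in the GRCh38.p14 RefSeq gene table, which was used for names and gene classes only, and 0 symbols needed updating. Probe sets whose mean over the 4 arrays lay below the 40th percentile of all probe sets (4.86 on the log2 scale) were left out. This kept 15349 probe sets and 14635 genes. Where several probe sets carried a symbol, the one with the highest mean stood for the gene. No further normalization was applied. Genes that share near-identical copies, such as the metallothioneins, HSPA1A and HSPA1B, and the CLEC18 family, have values that can mix the copies.

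Rapamycin and control arrays were compared with limma 3.58.1 in R 4.3.3. A linear model with group as the only term was fitted to the log2 values of all 4 arrays, and variances were moderated with eBayes with a mean-variance trend. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05, and every adjusted p for a gene comes from this limma fit unless another setting is named. Log2 fold changes are rapamycin minus control, given with the standard error (SE) of the moderated fit. The fit had 2 residual degrees of freedom per gene, to which the moderation added 7.27. The median SE of a log2 fold change was 0.12 and the median half-width of its 95% interval was 0.27. The number of arrays limits this precision.

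On simulated data with the spread of these 14635 genes, 2 arrays against 2 and 200 changed genes in each of 20 simulations, the same code recovered 15.9% of genes changed by 0.4 on the log2 scale. It recovered 68.1% of those changed by 0.7, 95.9% at 1 and 99.8% at 1.5, and 4.88% of the calls were false on average. With no gene changed, at most 1 gene and at most 1 gene list were called in any simulation. The simulated spread followed the model that limma assumes, and each gene was drawn independently of the others. The simulated list count therefore cannot show how often lists are called falsely when their genes vary together.

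The fit, the filter, the gene lists, the genes to name and the alternative settings were fixed before the data were examined. The 36 gene lists cover metabolism, stress responses, growth, the cell cycle, leukemic signalling, myeloid differentiation, other cell types and housekeeping genes. They hold 862 genes, of which 783 were matched to a probe set and 79 were not analysed here. The lists were compiled from textbook knowledge and not from these arrays. Each list was tested with camera from limma, two-sided, with a preset inter-gene correlation of 0.01, against all other genes, and adjusted over the 36 lists. Camera was repeated with a correlation estimated for each list. In that setting it tests on the 2 residual degrees of freedom of the fit, whatever the correlation. A list can then hardly pass an adjustment over 36 lists. A missed call there does not show that genes varying together gave the shift. Fry from limma was run to test whether a list's genes moved on balance one way, with no comparison against other genes. Counts adjusted over the list alone use the Benjamini-Hochberg method within a list.

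The genes named are the 12 highest and the 12 lowest log2 fold changes among called genes whose rapamycin arrays both lay beyond both control arrays, the 3 members with the smallest unadjusted p from each list (1 for lists of other cell types and for the housekeeping list), and a fixed set of genes for glucose metabolism, mTORC1 and leukemic signalling. Other genes that are named were chosen after their values were seen, and this is said where they appear. The rule named 122 genes with values, 54 of them called. Alternatives changed the filter, the normalization between arrays, the moderation of variances, the threshold, the rule for several probe sets of a gene, the set test and the replicate block, and left out each array in turn. Where an array was left out, the lone array of its group was assumed to vary like the other group. A test on protein-coding genes only was added after seeing the data. Figures were drawn with matplotlib 3.10.9.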

Results

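MOLM-14 is a human acute myeloid leukemia cell line that carries an activating internal duplication of the receptor tyrosine kinase FLT3 and a fusion of KMT2A (MLL). Rapamycin binds FKBP12 and blocks mTORC1, the kinase complex that couples nutrients and growth factors to protein, lipid and nucleotide synthesis. The data comprise genome-wide expression in 2 control arrays and 2 arrays from cells given 10 nM rapamycin for 24 hours. The comparison asks which transcripts differ after rapamycin in these cells, and no measurement of mTORC1 activity was used here. Array medians were 5.44 and 5.38 log2 units in the controls and 5.43 and 5.45 with rapamycin. Over all 25582 probe sets, before the filter, the control arrays correlated at 0.996 and the rapamycin arrays at 0.994. Correlations between the groups ran from 0.9924 to 0.9943, so the highest of them lay above the 0.9940 of the rapamycin pair. The principal component with the largest variance (54.6%) separated the groups, with control scores of -10.3 and -13.0 against 5.50 and 17.8 with rapamycin. The next component (26.3%) separated the rapamycin arrays from each other, at 14.5 and -8.47.

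Of 14635 genes tested, 187 changed, 61 upward and 126 downward, and 108 of them by at least 1.5-fold. At least 2-fold changes were found for 21 genes, 4 higher and 17 lower. The strongest fall was that of HSPA1B, an inducible cytosolic HSP70 chaperone, from 10.79 ± 0.06 to 8.53 ± 0.09 log2 units (SD, n = 2), which is 4.79-fold lower. The strongest rise was that of OCSTAMP, a membrane protein of cell fusion in osteoclasts, from 5.61 ± 0.07 to 7.12 ± 0.05 (SD, n = 2), which is 2.86-fold higher. PIM1, a survival kinase, rose 2.68-fold, from 8.58 ± 0.05 to 10.00 ± 0.10 (SD, n = 2). In all 187 called genes both rapamycin arrays lay on the same side of both control arrays. That held for 46.8% of all genes tested, against the 33.3% that chance gives for 2 against 2.

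Metallothioneins, small cysteine-rich proteins that bind zinc and copper, made up 5 of the 12 largest falls. MT1G fell 3.58-fold (log2 fold change -1.84, SE 0.10, adjusted p = 5.57e-05), MT2A fell 2.84-fold, MT1F 2.75-fold, MT1E 2.54-fold and MT1X 2.20-fold. S100A8, a calcium-binding protein of myeloid cells, fell 3.20-fold, from 8.08 ± 0.01 to 6.41 ± 0.10 log2 units (SD, n = 2). RGS2, a brake on G protein signalling, fell 2.61-fold (adjusted p = 0.00318), and the arrestin-like ARRDC3 fell 2.45-fold (adjusted p = 0.00248). GPNMB, a lysosomal glycoprotein, fell 2.12-fold (adjusted p = 0.00706). The non-coding CERNA2 and AMZ2P1 completed the 12 largest falls, at log2 fold changes of -1.16 and -1.15. Both had low signal, with rapamycin means of 4.42 and 4.48, under the filter minimum of 4.86. CERNA2 missed the filter without control replicate 1, and AMZ2P1 without control replicate 2. Sequences within the metallothionein and HSP70 families are nearly alike, so the share of each copy in these values is uncertain.

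After OCSTAMP and PIM1, the largest rise of a protein-coding gene was that of TLR2. TLR2, a receptor for bacterial lipoproteins, rose 2.09-fold (log2 fold change 1.07, SE 0.09, adjusted p = 0.00166), from 7.41 ± 0.11 to 8.47 ± 0.03 log2 units (SD, n = 2). TNF, the inflammatory cytokine, rose 1.91-fold (log2 fold change 0.93, SE 0.12, adjusted p = 0.00827). GPR84, a receptor for medium-chain fatty acids, rose 1.84-fold. TXNIP, which restrains glucose uptake, rose 1.93-fold, from 9.93 ± 0.19 to 10.88 ± 0.25 (SD, n = 2). Non-coding genes and pseudogenes supplied 5 of the 12 largest rises: MIR221 (2.65-fold), MIR223 (1.88-fold), ANKRD18DP (1.84-fold), RUNX1-IT1 (1.83-fold) and MIR4747 (1.78-fold). The probe sets of the MIR genes read precursor or host transcripts, not mature microRNAs. CLEC18A rose 1.74-fold, with near-identical family members that can share its probes. MIR4747 lost its call without control replicate 1 (adjusted p = 0.0524) or rapamycin replicate 2 (adjusted p = 0.0622), and CLEC18A without control replicate 2 (adjusted p = 0.127) or rapamycin replicate 2 (adjusted p = 0.082).

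**Figure D1:**
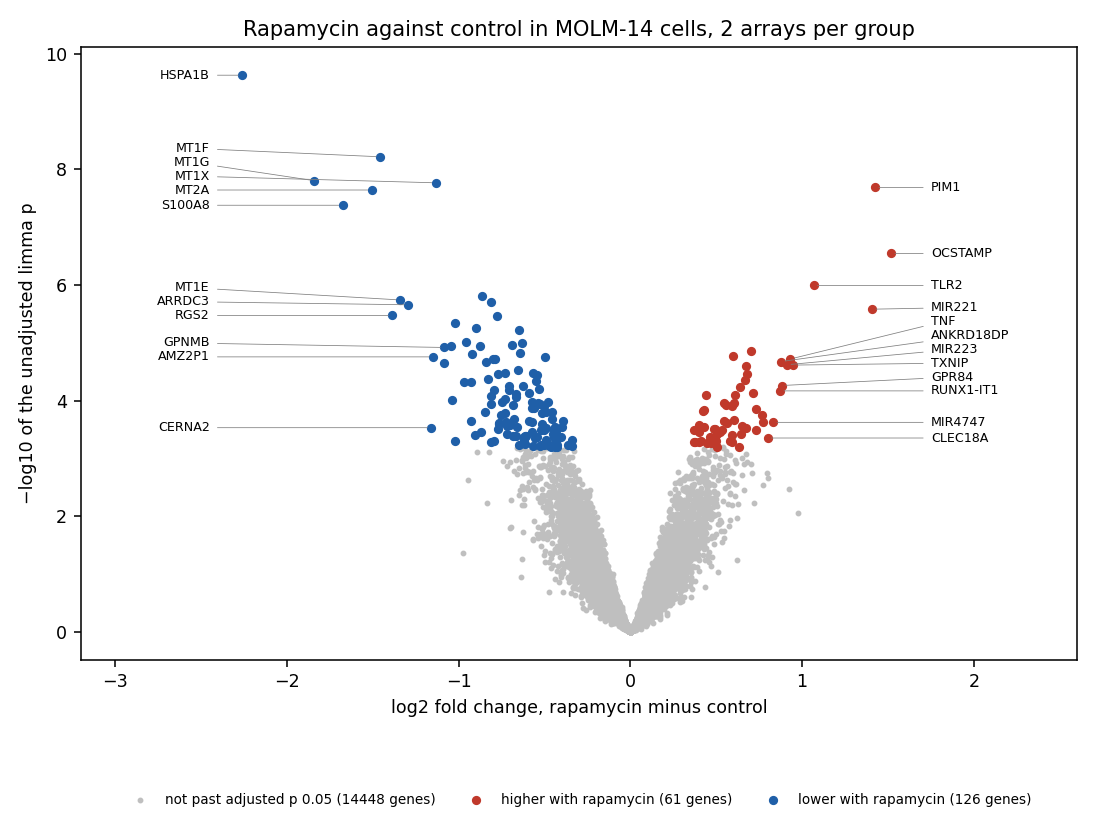
Log2 fold change (rapamycin minus control) on the horizontal axis against -log10 of the unadjusted limma p on the vertical axis, 1 point per gene tested. Red points mark the 61 genes that rose, blue points the 126 that fell and grey points the genes that did not pass. The 12 largest changes of each direction carry their symbols, with HSPA1B farthest to the left.

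Of 20 measured genes of glycolysis and glucose uptake, 5 fell and 15 did not pass, with 0 that rose. As a list they had a median log2 fold change of -0.17 and a camera adjusted p of 6.49e-08, and adjusted p = 0.415 with an estimated correlation. HK2, which traps glucose as glucose 6-phosphate, fell from 9.89 ± 0.10 to 9.20 ± 0.06 log2 units (SD, n = 2; 1.61-fold lower; adjusted p = 0.00703). PFKFB4, which makes the activator of phosphofructokinase, fell 1.66-fold (adjusted p = 0.0113), the glucose transporter SLC2A1 fell 1.49-fold (adjusted p = 0.024) and lactate dehydrogenase A (LDHA) fell 1.42-fold (adjusted p = 0.0378). The other called member was ALDOC, named after its value was seen, at a log2 fold change of -0.49. With no filter 2 members fell, and 0 without the mean-variance trend. Adjusted over the list alone, 6 members fell and 0 rose. The count of members that fell was 1 (HK2) without control replicate 2, 3 without control replicate 1, 5 without rapamycin replicate 2 and 7 without rapamycin replicate 1. SLC2A1 had an adjusted p of 0.134 and PFKFB4 of 0.0564 without control replicate 2, ALDOC had 0.126 and 0.214 without control replicates 1 and 2, and LDHA had 0.109 and 0.256.

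Among HIF1A targets outside glycolysis, 3 of 15 measured members fell and 1 rose, with 11 that did not pass. The median of the list was -0.34, with a camera adjusted p of 4.39e-08, and adjusted p = 0.415 with an estimated correlation. The number that fell was 7 with each array centred on its median, 8 with the replicate block and 6 among protein-coding genes alone, but 0 with no filter or without the mean-variance trend. ADM, which encodes the secreted peptide adrenomedullin, fell 2.05-fold, from 9.05 ± 0.22 to 8.01 ± 0.36 log2 units (SD, n = 2; adjusted p = 0.0208), the histone demethylase KDM3A fell by 0.48 on the log2 scale (SE 0.07, adjusted p = 0.0216), and the angiogenic factor VEGFA, named after its value was seen, fell by 0.44 (SE 0.08, adjusted p = 0.0462). The riser was TXNIP, which is also induced by glucose through other regulators. 11 members fell and 1 rose when adjusted over the list alone. Without control replicate 2 the count that fell was 1 (KDM3A had an adjusted p of 0.131 and VEGFA of 0.349), and without rapamycin replicate 1 it was 10. HIF1A itself had a log2 fold change of -0.24 (adjusted p = 0.257).

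The pentose phosphate pathway, which supplies NADPH and ribose, gave no called member among 11 measured. The log2 fold changes were -0.08 for PGD (SE 0.07, adjusted p = 0.658), -0.12 for TKT (adjusted p = 0.481), 0.34 for H6PD (adjusted p = 0.178) and 0.30 for PGLS (adjusted p = 0.292). Its median was -0.06 and its mean 0.01, which differ in sign, and camera gave an adjusted p of 0.993. Adjusted over the list alone, 0 rose and 0 fell.

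Of 19 measured genes of cholesterol synthesis and other SREBF2 targets, 5 fell, 0 rose and 14 did not pass. The list median was -0.22, with a camera adjusted p of 2.94e-09, and adjusted p = 0.405 with an estimated correlation. MSMO1, a sterol demethylation enzyme, fell from 9.98 ± 0.15 to 9.08 ± 0.13 log2 units (SD, n = 2; 1.87-fold lower; adjusted p = 0.0045). INSIG1, the sterol-regulated anchor of the SREBP pathway, fell 1.76-fold (SE 0.08 on the log2 scale, adjusted p = 0.00237) and the lanosterol demethylase CYP51A1 fell 1.45-fold (adjusted p = 0.0168). STARD4 and HMGCS1, named after their values were seen, also fell, at log2 fold changes of -0.75 and -0.72. With no filter 3 members fell, and 0 without the mean-variance trend. 9 members fell and 0 rose when adjusted over the list alone. Without control replicate 2 the number that fell was 3, as CYP51A1 (adjusted p = 0.117) and HMGCS1 (adjusted p = 0.0815) no longer passed.

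Fatty acid synthesis and SREBF1 targets included 3 genes that fell among 14 measured, with 0 that rose. They were the desaturases FADS2 (1.84-fold lower, log2 fold change -0.88, SE 0.10, adjusted p = 0.00703) and SCD (1.41-fold lower, SE 0.06, adjusted p = 0.00827) and the NADPH-producing malic enzyme ME1 (1.90-fold lower, SE 0.13, adjusted p = 0.0135). SCD moved from 11.59 ± 0.03 to 11.10 ± 0.01 log2 units (SD, n = 2). These 3 falls passed without each array in turn and when adjusted over the list alone, and 1 of them without the mean-variance trend. The median of the list was -0.13, camera gave an adjusted p of 0.0042, and adjusted p = 0.415 with an estimated correlation. With the filter raised to the 60th percentile the list had a camera adjusted p of 0.0638. By fry, which tests a list against no change and not against other genes, the adjusted p was 0.0418.

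**Figure D2:**
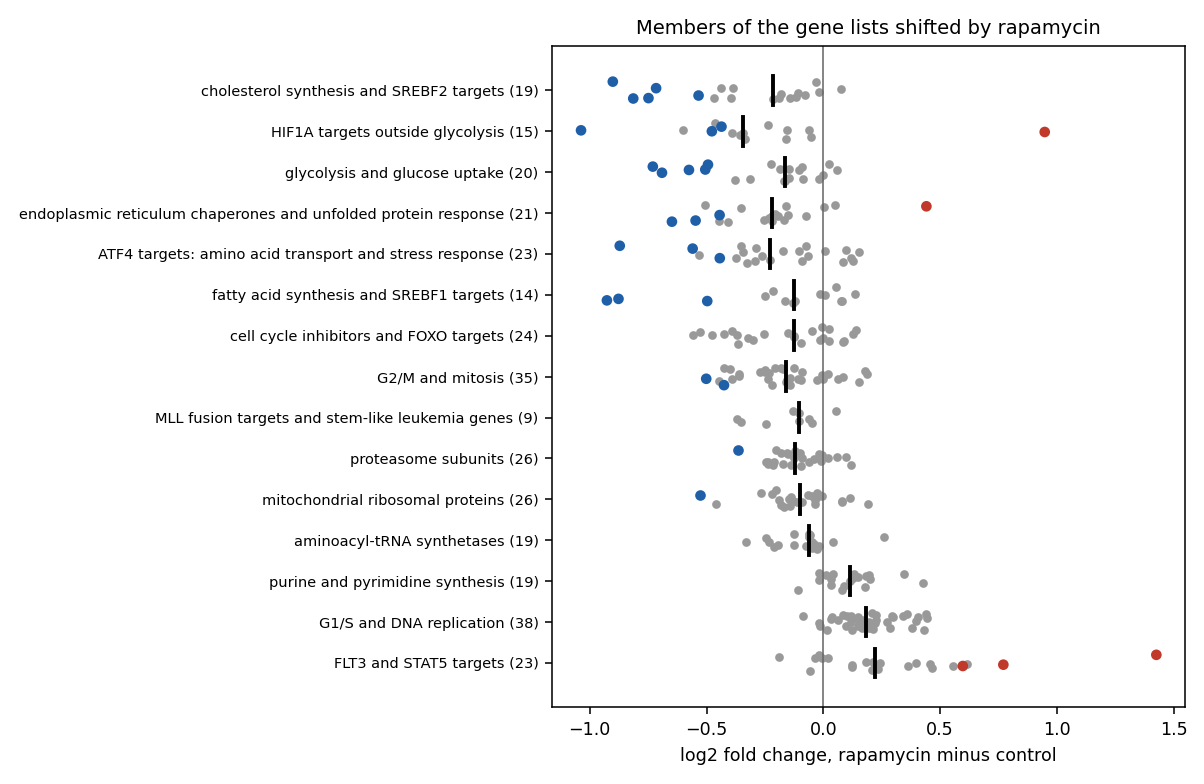
Log2 fold change (rapamycin minus control) on the horizontal axis for each measured member of the 15 gene lists called by camera, 1 list per row. Red points rose, blue points fell, grey points did not pass, and the black bar is the list median, which runs from -0.34 for HIF1A targets to 0.22 for FLT3 and STAT5 targets.

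Among endoplasmic reticulum chaperones and genes of the unfolded protein response, 3 of 21 measured members fell, 1 rose and 17 did not pass. The median was -0.22, camera gave an adjusted p of 1.38e-08, and adjusted p = 0.405 with an estimated correlation. The number that fell was 5 with each array centred on its median, with the replicate block or among protein-coding genes alone. It was 2 with no filter and 0 without the mean-variance trend, with 0 that rose in both. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 10.51 ± 0.02 to 9.87 ± 0.07 log2 units (SD, n = 2; 1.57-fold lower; adjusted p = 0.00456). The coat protein SEC24D fell 1.46-fold (adjusted p = 0.0115), and EDEM1, named after its value was seen, fell by 0.44 on the log2 scale (adjusted p = 0.0375). XBP1, a transcription factor of this response, rose 1.36-fold (log2 fold change 0.44, SE 0.07, adjusted p = 0.0182). By fry, with no comparison against other genes, the adjusted p was 0.012. Adjusted over the list alone, 12 fell and 1 rose. Without control replicate 2, HSPA5 was the only member past the test, and SEC24D had an adjusted p of 0.0719, XBP1 of 0.0579 and EDEM1 of 0.303. EDEM1 had an adjusted p of 0.139 without control replicate 1, and 6 members fell without rapamycin replicate 1.

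Of 23 measured ATF4 targets for amino acid transport and stress, 3 fell, 0 rose and 20 did not pass. The list median was -0.23, with a camera adjusted p of 1.82e-05, and adjusted p = 0.415 with an estimated correlation. None of them passed with no filter or without the mean-variance trend. The stress factor DDIT3 (CHOP) fell 1.83-fold, from 6.77 ± 0.10 to 5.90 ± 0.32 log2 units (SD, n = 2; adjusted p = 0.0391). DDIT4, an inhibitor of mTORC1, fell 1.47-fold (log2 fold change -0.56, SE 0.09, adjusted p = 0.0244), and the cystine transporter SLC7A11 fell by 0.44 on the log2 scale (adjusted p = 0.0381). 7 fell and 0 rose when adjusted over the list alone. Without control replicate 2 the count was 0, with adjusted p-values of 0.074 for DDIT3, 0.105 for DDIT4 and 0.303 for SLC7A11, and SLC7A11 also missed the threshold without control replicate 1 (adjusted p = 0.156). Without rapamycin replicate 2 the count that fell was 5, and without rapamycin replicate 1 it was 4, with 2 that rose.

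Of the 14 genes for serine, glycine and folate metabolism, 1 fell, the mitochondrial folate enzyme ALDH1L2 (log2 fold change -0.46, SE 0.07, adjusted p = 0.0264), and adjusted over the list alone 5 fell. CTH and PSAT1 had log2 fold changes of -0.51 (adjusted p = 0.116) and -0.21 (adjusted p = 0.178). The median was 0.00 and the mean -0.08, while camera pointed down with an adjusted p of 0.116, and of 0.415 with an estimated correlation. ALDH1L2 lost its call without control replicate 1 (adjusted p = 0.074) or control replicate 2 (adjusted p = 0.254), and with no filter. Aminoacyl-tRNA synthetases had 0 called members of 19, and adjusted over the list alone 1 rose and 1 fell. WARS1 had a log2 fold change of -0.33 (adjusted p = 0.0759), FARSA of -0.24 and QARS1 of 0.26. Camera gave an adjusted p of 0.0141 at a median of -0.06, and adjusted p = 0.415 with an estimated correlation. The call of this list was lost without control replicate 2 (adjusted p = 0.164), without rapamycin replicate 1 (adjusted p = 0.252) and after a repeated quantile normalization (adjusted p = 0.143).

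The lists of ribosome biogenesis and of cytosolic ribosomal proteins showed no called member. Ribosome biogenesis had 0 of 37 past the test (median log2 fold change 0.05, camera adjusted p = 0.623), with NOP56 at 0.25 and POLR1B at 0.17. The cytosolic ribosomal proteins had 0 of 22 (median 0.06, adjusted p = 0.356), with RPS19 at 0.11, RPS3 at 0.13 and RPL18 at 0.08. Adjusted over the list alone, 0 members of these lists passed. Among MYC and its direct targets, 1 of 18 fell, MXD1, a MAX partner that opposes MYC (1.55-fold lower, SE 0.09, adjusted p = 0.0154), with an adjusted p of 0.0967 without control replicate 2. MYC had a log2 fold change of 0.15 (adjusted p = 0.309), ODC1 of -0.40 (adjusted p = 0.0583) and NME2 of 0.24. That list had a median of 0.05 and a mean of -0.02, camera pointed down with an adjusted p of 0.998, and 2 members fell when adjusted over the list alone. Components and regulators of mTORC1 had 0 called members of 30 (median -0.01, adjusted p = 0.623), and 1 fell when adjusted over the list alone. MTOR stood at 0.15 (adjusted p = 0.509), RPTOR at 0.00 (adjusted p = 0.994), RRAGC at -0.45 (adjusted p = 0.0695) and DEPTOR at -0.39 (adjusted p = 0.196).

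Of 19 genes of purine and pyrimidine synthesis, 0 passed. The list median was 0.11, camera gave an adjusted p of 0.00938, and adjusted p = 0.415 with an estimated correlation. CTPS1, which makes CTP, had a log2 fold change of 0.43 (adjusted p = 0.052) and was the 1 member higher when adjusted over the list alone. 1 member rose with the stricter filter, with the replicate block or among protein-coding genes alone. IMPDH2 and TK1 stood at 0.18 and 0.35. Without rapamycin replicate 2 the camera adjusted p was 0.145.

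MRPL44 was the 1 of 26 mitochondrial ribosomal proteins that fell (log2 fold change -0.53, SE 0.10, adjusted p = 0.0497), with MRPL22 at -0.46 and MRPS22 at -0.27. The median was -0.10 (camera adjusted p = 0.00341, and adjusted p = 0.415 with an estimated correlation), and 2 fell when adjusted over the list alone. PSMD14 was the 1 of 26 proteasome subunits that fell (log2 fold change -0.37, SE 0.07, adjusted p = 0.0487), also when adjusted over the list alone. PSMA4 and PSMB1 stood at -0.21 and -0.20. The proteasome median was -0.12 (camera adjusted p = 0.00116, and adjusted p = 0.415 with an estimated correlation). Without control replicate 2 the mitochondrial ribosomal list had a camera adjusted p of 0.0847. Neither MRPL44 nor PSMD14 passed with no filter, after a repeated quantile normalization or with robust moderation. Without control replicates 1 and 2, MRPL44 had adjusted p-values of 0.0518 and 0.295, and PSMD14 of 0.283 and 0.322.

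In the tricarboxylic acid cycle list, 2 of 19 members fell, the cytosolic dehydrogenases IDH1 (1.42-fold lower, SE 0.08, adjusted p = 0.0225) and MDH1 (log2 fold change -0.43, SE 0.08, adjusted p = 0.0385), and the same count fell when adjusted over the list alone. IDH3B, a mitochondrial subunit, stood at -0.22. Neither called enzyme acts inside the mitochondrion. The median was -0.07 and camera gave an adjusted p of 0.0989, of 0.0469 with no filter, and of 0.415 with an estimated correlation. IDH1 had adjusted p-values of 0.115 and 0.126, and MDH1 of 0.204 and 0.166, without control replicates 1 and 2, and neither passed with no filter. The respiratory chain had 0 called members of 25 (median -0.06, camera adjusted p = 0.063, and adjusted p = 0.462 with an estimated correlation). COX5B stood at -0.37 (adjusted p = 0.0757), and 1 member fell when adjusted over the list alone. NDUFV2 and NDUFS3 stood at -0.63 (SE 0.29) and -0.20 (SE 0.11), but differed between the rapamycin arrays. NDUFV2 was at -1.18 (adjusted p = 0.00254) without rapamycin replicate 1 and at -0.08 without rapamycin replicate 2, and NDUFS3 at -0.05 and -0.35. The respiratory chain list was called without control replicate 1 (adjusted p = 0.0457), without rapamycin replicate 2 (adjusted p = 0.00395) and with no filter (adjusted p = 0.0221).

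Lysosome and autophagy genes controlled by TFEB had 2 of 36 members that fell, 0 that rose and a median of -0.04. Camera gave an adjusted p of 0.141, and adjusted p = 0.415 with an estimated correlation. GPNMB is given above, and the protease CTSB fell by 0.40 on the log2 scale (SE 0.07, adjusted p = 0.0337). LAMP2 had a log2 fold change of -0.42 (adjusted p = 0.0528). 6 fell and 2 rose when adjusted over the list alone. CTSB lost its call without control replicate 1 (adjusted p = 0.0808) or control replicate 2 (adjusted p = 0.16), and the list was called without rapamycin replicate 2 (adjusted p = 0.0405). The NFE2L2 antioxidant list had 2 of 18 members that fell, ME1 and SLC7A11, which other lists hold too, and NQO1 stood at -0.60 (adjusted p = 0.0583). Its median was -0.08 (camera adjusted p = 0.103, and adjusted p = 0.607 with an estimated correlation), and 4 fell when adjusted over the list alone. Without control replicate 1 or rapamycin replicate 2 the camera adjusted p was 0.0319 and 0.0405.

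**Figure D3:**
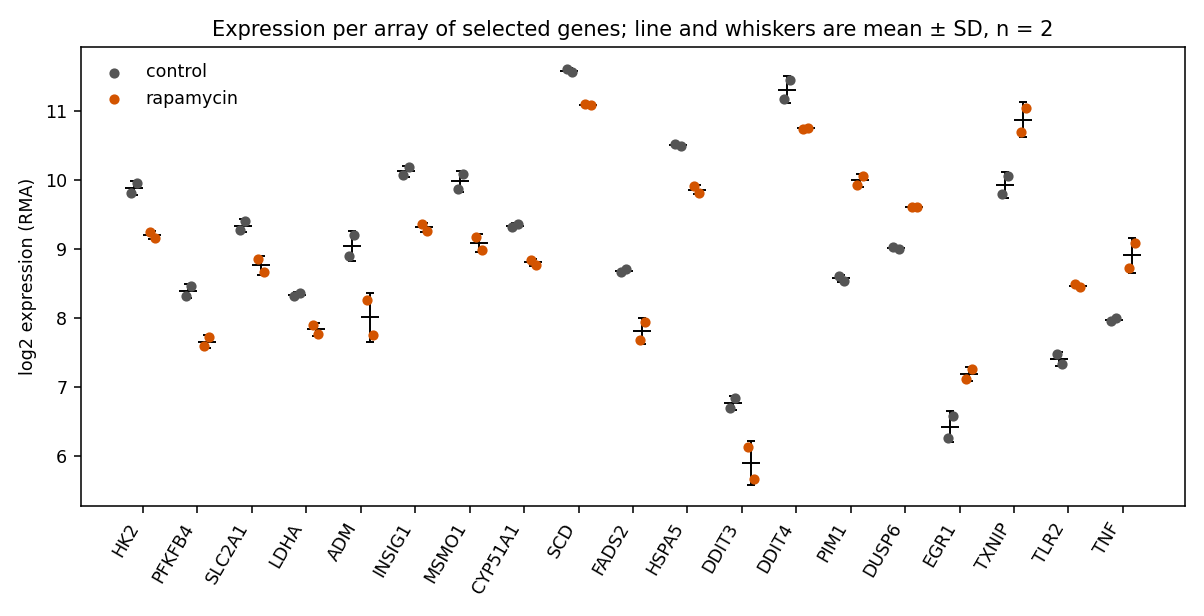
Log2 RMA value of 19 named genes on each of the 4 arrays, with the mean and SD of each group (n = 2). Points are single arrays. PIM1 lies near 8.58 in the controls and 10.00 with rapamycin, and HSPA5 near 10.51 and 9.87.

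Of 38 genes of G1/S and DNA replication, 35 lay above 0 but 0 passed the test over all genes. The list median was 0.18, camera gave an adjusted p of 8.54e-09, and adjusted p = 0.405 with an estimated correlation. Adjusted over the list alone, 10 rose. The cyclins CCNE2 and CCND3 had log2 fold changes of 0.40 (SE 0.09, adjusted p = 0.0652) and 0.44 (SE 0.10, adjusted p = 0.0845), and the primase subunit PRIM1 of 0.29 (adjusted p = 0.0877). Of 35 genes of G2/M and mitosis, 2 fell and 0 rose, and 7 fell when adjusted over the list alone. The G2/M median was -0.16, camera gave an adjusted p of 3.35e-06, and adjusted p = 0.415 with an estimated correlation. The number that fell was 5 with each array centred on its median, the stricter filter, the replicate block or protein-coding genes alone. It was 1 after a repeated quantile normalization, and 0 with no filter, with robust moderation or without the mean-variance trend. NEK2, a centrosome kinase, fell 1.42-fold (log2 fold change -0.50, SE 0.10, adjusted p = 0.0487) and CKS2, a CDK subunit, fell by 0.43 on the log2 scale (SE 0.08, adjusted p = 0.0487). HMMR stood at -0.45 (adjusted p = 0.0559). NEK2 lost its call without control replicate 1 (adjusted p = 0.173), control replicate 2 (adjusted p = 0.275) or rapamycin replicate 2 (adjusted p = 0.0536), and CKS2 without control replicate 2 (adjusted p = 0.4). Without rapamycin replicate 1, 12 G2/M members fell and 7 G1/S members rose.

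Among cell cycle inhibitors and FOXO targets, 0 of 24 members passed the test over all genes and 7 fell when adjusted over the list alone. The median was -0.13, camera gave an adjusted p of 0.000403, and adjusted p = 0.415 with an estimated correlation. 4 members fell with each array centred on its median, 3 with the replicate block, and 1 with the stricter filter or among protein-coding genes alone. CCNG2 had a log2 fold change of -0.56 (SE 0.11, adjusted p = 0.0559), GADD45A of -0.39 (adjusted p = 0.0753) and SESN1 of -0.42 (adjusted p = 0.0754). Without rapamycin replicate 1, 5 members fell.

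Of 23 measured FLT3 and STAT5 targets, 3 rose, 0 fell and 20 did not pass, and 11 rose when adjusted over the list alone. The list median was 0.22, camera gave an adjusted p of 1.80e-07, and adjusted p = 0.405 with an estimated correlation. The number that rose was 5 with each array centred on its median or among protein-coding genes alone, and 1 without the mean-variance trend. PIM1 rose 2.68-fold (log2 fold change 1.42, SE 0.08, adjusted p = 5.57e-05). DUSP6, a phosphatase that switches off ERK, rose 1.51-fold, from 9.02 ± 0.03 to 9.62 ± 0.00 log2 units (SD, n = 2; adjusted p = 0.00827), and the immediate early factor EGR1 rose 1.71-fold (SE 0.13, adjusted p = 0.0337). CISH and SPRY4, named after their values were seen, had log2 fold changes of 0.56 (adjusted p = 0.0528) and 0.61 (adjusted p = 0.064). FLT3 itself stood at 0.24 (adjusted p = 0.16) and PIM2, the gene that the growth protocols name, at 0.24 (SE 0.09, adjusted p = 0.233). EGR1 had an adjusted p of 0.0867 without control replicate 1, and without rapamycin replicate 1 the number of members that rose was 6.

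MLL fusion targets and stem-like leukemia genes had 0 called members of 9, with a median of -0.10. SENP6 stood at -0.35 (adjusted p = 0.078), MEIS1 at -0.37 and RUNX2 at -0.25, and 1 fell when adjusted over the list alone. Camera gave an adjusted p of 0.0087, and adjusted p = 0.415 with an estimated correlation. That call was lost without control replicate 2 (adjusted p = 0.0558) or rapamycin replicate 2 (adjusted p = 0.0595). Regulators of apoptosis had 0 called members of 22 (median 0.00, camera adjusted p = 0.623), with BCL2A1 at -0.56 (adjusted p = 0.0874), CFLAR at 0.32 and BCL2 at 0.26. 1 rose and 1 fell when adjusted over the list alone.

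Myeloid differentiation markers did not move as lists. Of 16 monocyte and macrophage markers, TLR2 rose and S100A8 fell, over all genes and adjusted over the list alone (median -0.12, camera adjusted p = 0.195), and CSF1R stood at 0.34 (adjusted p = 0.178). Of 12 granulocyte markers, 1 fell, the azurophil granule protease CTSG, from 10.30 ± 0.11 to 9.65 ± 0.12 log2 units (SD, n = 2; 1.58-fold lower; adjusted p = 0.0106), with the same count when adjusted over the list alone (median -0.07, camera adjusted p = 0.538). MMP9 stood at 0.44 and BPI at -0.26. HLA class II genes had 0 called members of 11 (median -0.09, camera adjusted p = 0.0909), with HLA-DRA at -0.44, HLA-DMA at -0.29 and HLA-DMB at -0.19. In the NF-kB and cytokine list, TNF was the 1 of 13 that rose, with IER3 at 0.67 (adjusted p = 0.0559) and NFKB1 at -0.30. The median was -0.03 and the mean 0.05, and camera pointed down with an adjusted p of 0.682. Adjusted over the list alone, 2 of these rose and 3 fell. Interferon response genes had 0 called members of 20 (median -0.09, adjusted p = 0.0942), with IFI6 at -0.25, TAP1 at -0.18 and IFIH1 at -0.18. That list had a camera adjusted p of 0.0238 with no filter, and of 0.415 with the filter and an estimated correlation.

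Markers of other cell types gave no call. T and NK cell markers had 0 of 6 (median 0.00, camera adjusted p = 0.782; CD5 at 0.18) and B cell markers 0 of 8 (median -0.04, adjusted p = 0.393; BANK1 at -0.24). Erythroid and megakaryocyte markers had 0 of 7 (median -0.11, adjusted p = 0.299; TFRC at -0.11), and fibroblast and epithelial markers 0 of 9 (median 0.00, adjusted p = 0.993; COL6A3 at -0.33). The fibroblast and epithelial list had a median and a mean at or just above 0 while camera pointed down. Housekeeping genes had 0 of 20 past the test (median -0.05, adjusted p = 0.148; PPIB at -0.26). 0 members of these 5 lists, of the HLA class II list or of the interferon list passed when adjusted over the list alone.

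In all, camera called 15 of the 36 lists, 12 lower and 3 higher. None was called with an estimated correlation, where 4 lists had an unadjusted p under 0.05. That setting tests on 2 degrees of freedom and could hardly call any list. The number of called genes rests on borrowing variance across genes, with 17 genes when the mean-variance trend is left out and 0 by an ordinary linear model, in which 1438 genes had an unadjusted p under 0.05. It also depends on single arrays, with 156 called genes without control replicate 1, 76 without control replicate 2, 1300 without rapamycin replicate 1 and 298 without rapamycin replicate 2. Of the 187 genes, 56 were called in each of these 4 fits, among them HSPA1B, MT1G, S100A8, PIM1, TLR2, HK2, INSIG1, MSMO1, SCD, FADS2 and HSPA5.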

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

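Of 713 probe sets with no gene symbol that passed the filter, 5 changed with rapamycin at an adjusted p under 0.05 in the limma fit over all probe sets, a signal outside the gene-level comparison. Of these, 3 were higher and 2 lower, and the largest size was 0.95 on the log2 scale. They have no name here and no explanation was tested.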

How the results depend on the processing

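Every called gene that was tested kept its sign under every alternative, while the number of calls moved widely. For most alternatives the sign was settled in advance. Filters, thresholds, moderation and the replicate block leave a fold change as it is. Leaving out 1 array cannot turn the sign where both rapamycin arrays lie beyond both control arrays, as in all 187 genes. Only the changes of normalization could turn it broadly, here and for the named genes below. The mean of a gene's probe sets tests little, as 24244 probe sets carried 24241 distinct symbols. Counts are given as genes called, higher, lower, and probe sets called, against 187, 61, 126 and 178. With no filter they were 60, 17, 43 and 56, where 24241 genes share the adjustment. Without a mean-variance trend they were 17, 4, 13 and 17, all 17 genes being among the 187. With no moderation limma's linear model gave 0 of each, with 1438 genes at an unadjusted p under 0.05. An adjusted p under 0.1 gave 431, 174, 257 and 455, and a 1.5-fold minimum on top of the adjusted p gave 108, 33, 75 and 109. Centring each array on its median gave 317 genes, 79 higher and 238 lower, and 322 probe sets. The share of calls that were higher was then 24.9%, against 32.6%, and the median of all genes shifted by -0.03. Repeated quantile normalization gave a share of 37.5%. The stricter filter, repeated quantile normalization, robust moderation, an unadjusted p with a 1.5-fold minimum and the mean of a gene's probe sets left these counts within 1.5 times of those reported. So did protein-coding genes alone (232 genes), a setting added after the data were seen. For the changes of normalization and moderation the cause was not tested. With 1 array left out, the counts ran from 76 to 1300 genes, 29 to 443 higher, 47 to 857 lower, 67 to 1356 probe sets and 12 to 17 gene lists. The 107, 62, 187 and 171 genes shared with the reported calls are those without control 1, control 2, rapamycin 1 and rapamycin 2. The cause of these differences was not tested. The SD over genes of the difference between arrays was 0.215 for the rapamycin pair and 0.173 for the controls.

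Both groups carry replicate numbers 1 and 2, and the labels do not say what a number shares. Same-numbered arrays did not deviate together (correlation over genes -0.0288). With 2 arrays per group this cannot exclude a shared culture day or batch. With the replicate block 321 genes were called, 116 higher and 205 lower, among them all 187, and 15 lists. The calls of the 15 lists ended with an estimated correlation (0 lists, 4 at an unadjusted p under 0.05), and fry, whose null is no change, called 2. Camera with an estimated correlation has only 2 degrees of freedom, so this loss cannot be laid to correlation alone. The estimate lay below the preset 0.01 for fatty acid synthesis (-0.074), FLT3 and STAT5 targets (-0.014) and endoplasmic reticulum chaperones (-0.0038). It lay above 0.01 for the other called lists, up to 0.319. The preset value remains an assumption. Among the 54 called genes that the rule named, 715 of 903 values under alternatives stayed past the threshold, 188 did not and 0 changed sign. RPTOR, near 0 throughout, turned to -0.0061 after repeated quantile normalization and -0.0275 after centring, and ran from -0.0702 to 0.0770 with 1 array left out. The cause was not tested.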

Other observations

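The test of SLC30A1 below, the narrower class of non-coding genes and the shorter MondoA lists were chosen after the results were seen, and the patterns themselves were noticed in these data. Several called genes outside the fixed lists are described here, also chosen after their values were seen. The AP-1 subunit JUND rose by 0.64 on the log2 scale (SE 0.09, adjusted p = 0.0154 in limma), and SAT1, the rate-limiting enzyme of polyamine breakdown, fell by 1.04 (SE 0.12, adjusted p = 0.00703). PPP1R15A, a phosphatase subunit of the integrated stress response, fell by 0.79 (SE 0.10, adjusted p = 0.00827), and the lipid mediator protein ANXA1 fell by 0.92 (SE 0.11, adjusted p = 0.00817). RUNX1, the host of the intronic RUNX1-IT1, had a log2 fold change of 0.42 (SE 0.07, adjusted p = 0.0264), with adjusted p-values of 0.115 and 0.169 without control replicates 1 and 2.

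The 5 measured metallothioneins (median -1.46), SLC30A1 and the heat shock genes HSPA1B and DNAJB1 fell with rapamycin. Whether the metallothionein probe sets read separate copies or shared signal stays open, because SLC30A1 (upper 95% bound -0.68), a zinc exporter of unrelated sequence, was picked for its fall and says nothing of the copies. Shared signal between HSPA1 copies stays open too, because the fold changes of other genes do not show which copy a probe set reads. The other heat shock factor targets had a median of only -0.11 (bootstrap interval -0.21 to -0.01, camera p = 0.00151, or 0.0771 with an estimated correlation) with 0 of 15 called. A single array does not carry the pattern, since 100% of its 8 called genes stayed called without each array in turn. A difference in metal, temperature or handling between the cultures cannot be told apart from the treatment, because both would give a group difference above the spread (for the metallothioneins at least 5.77 times the difference within a group).

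Genes not annotated as protein-coding made up 21 of the 61 genes that rose (34.4%) and 8 of the 126 that fell (6.35%). Their share of genes tested was 15.1%. The odds ratio of risers against fallers was 7.64 (Fisher's exact p = 1.98e-06, two-sided). That of risers against all other genes tested was smaller, at 2.97 (Fisher's exact p = 0.000185). The larger ratio thus also holds the low share among the fallers. A narrower class left out 19 genes of unknown class, 1 of them a riser, and 82 immunoglobulin and T cell receptor segments. Non-coding RNA genes and pseudogenes then made up 20 of 60 risers and 8 of 126 fallers (odds ratio 7.28, Fisher's exact p = 4.43e-06). The uncalled genes of the wider class lay 0.036 above the uncalled protein-coding genes. The 95% bootstrap interval was 0.0283 to 0.0443, and 0.0297 to 0.0439 for the narrower class. A shift of the whole class was thus seen in these arrays, and its small size argues against it as the full cause. The intervals and exact tests of this paragraph treat genes as independent and do not measure the spread between arrays. Lower signal is argued against, for risers against fallers, by an odds ratio of 8.71 within 3 strata of mean expression (95% interval 3.16 to 26.8, exact p = 2.60e-06), and of 8.29 for the narrower class. More unspliced or degraded RNA in the rapamycin samples was not tested and stays open.

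G1/S genes were higher and G2/M genes lower as lists by camera with the preset correlation, and 0 of 38 G1/S and 2 of 35 G2/M genes passed. Neither list was called with an estimated correlation (adjusted p = 0.405 and adjusted p = 0.415), a setting that could hardly call any list. A trend with signal intensity is argued against by the percentile of the G1/S median, which was 100 among 10000 random lists matched on mean expression, and that of the G2/M median was 0. A single array is argued against at the preset correlation, where the largest adjusted camera p of either list with an array left out was 0.00308. What stays open is a difference in cell cycle state between cultures that arose without the drug, because the labels give no culture or batch apart from the treatment. A shift of cells from G2/M toward G1 under rapamycin may also give this pattern, and no measurement of phase was used here.

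The rises of PIM1, DUSP6 and EGR1 may reflect relief of feedback on ERK signalling, a hypothesis that was tested on other genes known to be induced by ERK. Of 16 such genes, 14 had a log2 fold change above 0 and 0 were called, at a median of 0.10 (camera p = 0.0233, and p = 0.2 with an estimated correlation). The values go with the hypothesis weakly, and DUSP7 (log2 fold change 0.40, adjusted p = 0.0462, or 0.174 and 0.314 without control replicates 1 and 2) was seen beforehand.

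The joint rise of TXNIP and ARRDC4 (log2 fold change 0.73, SE 0.12, adjusted p = 0.0247, or 0.0745 without control replicate 2) might come from MondoA, a glucose-sensing factor that induces both. A list of 6 other genes gave a camera p of 0.434, but it held MLXIP, which encodes MondoA itself, and its paralog MLXIPL. Without MLXIP, 2 of 5 genes lay above 0, and without both, 1 of 4, with 0 called. These shorter lists also pointed down, with a camera p of 0.171 and 0.102, or 0.391 and 0.453 with an estimated correlation. The prediction thus failed, though genes this few that go both ways cannot settle the hypothesis. ARRDC3, a relative of ARRDC4, fell.

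The 4 arrays can be split into 2 and 2 in 3 ways, of which 1, the real one, called 187 genes, and the highest of the others called 0. With 3 splits a share under 0.05 cannot be reached.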
